A study of Danio rerio with 9 samples.

How the data were processed

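Total RNA was extracted from about 2000 embryos or larvae per stage, poly(A) RNA was purified, fragmented with RNase III and made into SOLiD fragment libraries, per the labels. The deposited table gives 1 RPKM value per Ensembl gene and stage, with 29291 genes and 9 columns, each matched to its stage by name. Per the submitters' processing notes the genome build was Zv9. The aligner, the counting program, the annotation release and any filters are not given in the sources used here. Symbols were taken from a table of gene IDs, which matched 19580 of the 29291 IDs. Many of its symbols are in upper case, and list members were matched without regard to case. A zebrafish genome of this build was not used here, so no coordinates are given, and genes with near-identical copies, such as the crystallins, trypsins and hox cognates, can share reads.

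Depth was recovered from the deposited RPKM values themselves, since RPKM is reads divided by gene length and by mapped reads. Mapped reads came out as whole numbers, and 99.9% of 1280 low genes then had a whole length, against 59.9% if totals were 2 times and 67.4% if they were 3 times as large. In 15452 of the 19868 genes past the filter (77.8%) the values in 8 libraries were whole reads over 1 length, to a relative tolerance of 1e-09. The other genes were not 1 read number over 1 length, and the sources used here do not say why. The Pec-fin values were sums of 2 steps, read here as the mean of runs of 171010360 and 59857652 mapped reads. That reading rests on the column total, which resembles those of its neighbours. Over 11598 genes the 2 runs differed with an SD of 0.077 on the log2 scale, and 0 genes differed by 2-fold. If these are runs of 1 library, which the labels do not say, this is run-to-run spread and no replicate error. Against the ratio of their totals, their reads gave a median chi-square per gene of 0.81, where counting noise alone gives 0.455. At the median recovered length of 2054 bases, 1 RPKM stood for 253 reads at 64-cell and 422 at Protruding-mouth. The exact 95% Poisson interval of 1 RPKM reached up to 1.13 at 64-cell and 1.10 at Protruding-mouth, and 3 reads, the floor, were 0.0118 and 0.00711 RPKM. No interval is given for Pec-fin, whose values are means of 2 runs. Intervals and floors cover counting error only.

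Genes with at least 1 RPKM in 1 or more libraries were kept. Neighbouring stages were compared by the difference in log2(RPKM + 1), and a gene was counted as higher or lower at a difference of at least 2 (4-fold). With 1 library per stage no test between stages was made. Of 37 gene lists fixed in advance, 36 had at least 4 measured members, and adult globins did not. For each list the median difference was ranked among those of 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries, and a list stood apart at or below percentile 2.5 or at or above 97.5. List members were counted at 2-fold. All list medians quoted for RPKM as deposited stood apart. Genes were named by fixed rules. These took the 5 largest positive and 5 largest negative differences per step with a unique gene symbol and at least 10 RPKM in the higher library, the 3 most abundant genes per stage, the 5 highest stage-restricted genes per stage, and members of the lists beside their counts. Genes of the panel described in the closing observations were chosen after their values were seen. The tau index used log2(RPKM + 1). These choices, and the alternatives of another pseudocount (0.1), no filter, median-of-ratios scaling, scaling without the 100 most abundant genes, a threshold of 0.5 RPKM, Pearson correlation and leaving out mitochondrially encoded genes, were made before the data were examined. Leaving out the panel, using each Pec-fin run alone and a wider matching of list members were added after seeing the data.

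The code was tested on simulated data. In 5 simulated tables of 8000 genes the read recovery returned the mapped reads of 40 of 40 single-run libraries and both run totals in 5 of 5 tables. Lengths were scored only for genes simulated with 1 length, with reads in every single-run library and with a length found. Of these, 99.8% had the right length. Among genes with the right length, 99.8% of the 2-run values were split. An earlier form of the recovery failed this test, by returning a multiple of a true total or a wrong step for the second run, and was corrected. The values for these libraries were the same before and after. For the step from 64-cell to oblong-sphere, reads were redrawn for 15452 genes. Of 100 genes changed 8-fold, 100% were called at 4-fold, and 0 unchanged genes were called. The 100% does not extend to low genes, where an 8-fold change can fall short of the threshold in log2(RPKM + 1). The 0 calls cover counting noise only, and the Pec-fin runs differed by more than that (median chi-square 0.81 against 0.455). Of 200 random lists over 19868 genes, 6% stood apart. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.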

Results

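Poly(A) RNA from whole zebrafish embryos and larvae of the AB strain was sequenced at 9 stages, from cleavage to the first week of larval life, to follow gene expression through development. The stages were 64-cell (2 hours post-fertilization, hpf), oblong-sphere (3.6 to 4 hpf), 50%-epiboly (5.25 hpf), 15-somite (16.5 to 17.5 hpf), Prim-25 (36 hpf), Long-pec (48 hpf), Pec-fin (60 hpf), Protruding-mouth (72 hpf) and the 1-week larva. Each stage had 1 library made from about 2000 individuals. There are no replicates, so no difference between stages was tested, and every comparison describes these libraries alone. The values are RPKM, reads normalized to gene length and mapped reads, for 29291 genes, of which 19868 reached 1 RPKM in at least 1 library. Mapped reads, recovered from the values, came to between 123311411 (64-cell) and 205507592 (Protruding-mouth) for libraries of 1 run, and to 171010360 and 59857652 for the runs of Pec-fin. Differences are in log2(RPKM + 1), later minus earlier stage, which understates differences of low genes.

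Mitochondrially encoded genes led the libraries. MT-CO1, a subunit of cytochrome c oxidase, was the highest gene at the 64-cell (3653 RPKM), oblong-sphere (4289 RPKM) and 50%-epiboly (6332 RPKM) stages, and MT-CO2, another subunit, at 1 week (16959 RPKM). At 50%-epiboly HSPB1, a small heat shock protein, came next with 5998 RPKM, against 29.3 RPKM at oblong-sphere and 412 RPKM at 15-somite. RPS29, a ribosomal protein, reached 6893 RPKM at Pec-fin, and the muscle calcium buffer pvalb1 reached 8772 RPKM at 1 week. The 10 most abundant genes held 6.57% of the summed RPKM at 64-cell and 17.4% at Protruding-mouth. Genes at 1 RPKM or more numbered 11701, 11638, 10700, 13068, 13648, 13455, 13752, 15563 and 17381 from the first stage to the last. Spearman's rank correlation across genes, which are not independent replicates, was 0.951 between 64-cell and oblong-sphere, 0.722 between oblong-sphere and 50%-epiboly, 0.977 between Prim-25 and Long-pec, and 0.778 between Protruding-mouth and 1 week.

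Between the 64-cell and oblong-sphere stages, which span the start of zygotic transcription, early zygotic regulators were higher. Of 30 early zygotic and pluripotency genes, 20 were at least 2-fold higher and 0 lower, with a median difference of 2.1. The transcription factor genes klf17 (0.893 to 73.3 RPKM), SOX3 (0.0462 to 28.5 RPKM) and irx7 (0.0956 to 24.0 RPKM) were among the 5 genes with the largest positive differences, together with nnr and inka1a. Of 22 mesendoderm and organizer genes, 7 were at least 2-fold higher, among them dkk1b, a secreted Wnt inhibitor (0 to 5.74 RPKM), and tbx16, a T-box factor of the mesoderm (0.0202 to 4.55 RPKM). Of 35 maternal oocyte and germ plasm genes, 12 were at least 2-fold lower and 1 higher, with a median of -0.59. The egg coat gene zp3a.1 had 211 and then 25.1 RPKM, and DAZL, an RNA-binding protein of germ cells, had 101 and then 27.2 RPKM. All 6 vitellogenins, the yolk precursors, were at least 2-fold lower, with vtg1 at 15.0 and then 0.00498 RPKM. So were 14 of 25 exocrine pancreas enzymes (median -1.28) and 10 of 45 liver and plasma protein genes. A panel of 78 genes includes digestive, oocyte and gonad genes. It was chosen after seeing the data for values that were higher at Long-pec than at Prim-25 and Pec-fin. Its median was lower too, from 1.6 times its Long-pec level to 0.0813 times. Of the 78 genes, 43 were under 0.5 RPKM at oblong-sphere. The others were not, such as the oocyte gene DDX4 (70.8 and then 46.7 RPKM). The elastase gene ela3l had 13.2 and then 0.0217 RPKM, and fabp10a, a liver fatty acid binding protein, 20.6 and then 0.0116 RPKM. Altogether 74 genes were at least 4-fold higher and 136 at least 4-fold lower.

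The step from oblong-sphere to 50%-epiboly held the most genes past 4-fold, 1365 higher and 2928 lower. Maternal genes were far lower. Of the 35 maternal oocyte and germ plasm genes, 25 were at least 2-fold lower and 1 higher, with a median of -2.78. The claudin gene cldnd had 1048 and then 8.43 RPKM, and BTG4, an adaptor for deadenylation of maternal mRNA, had 257 and then 1.62 RPKM. Early zygotic and pluripotency genes went both ways, with 19 of 30 at least 2-fold higher and 6 lower (median 1.71), and among the lower ones nanog, a pluripotency factor, had 600 and then 17.5 RPKM. The other large negative differences belonged to cldng (-6.68), ccnp (-6.33) and cth1 (-6.11). Of 62 cell cycle and DNA replication genes, 25 were at least 2-fold lower and 10 higher, and CCNB2, a mitotic cyclin, had 473 and then 32.2 RPKM. In the other direction, 19 of 30 epidermal and ionocyte genes were at least 2-fold higher, with keratins krt4 (3.23 to 1886 RPKM) and krt5 (1.06 to 903.6 RPKM) in front. Mesendoderm and organizer genes had a median of 2.80, with 18 of 22 at least 2-fold higher. Examples are the BMP antagonist chrd (0.579 to 75.3 RPKM), the endoderm factor GATA5 (0.0319 to 42.4 RPKM) and eve1 (0.348 to 70.7 RPKM). The highest positive differences outside the keratins were those of the protease gene ctsll (9.45), fetub (9.01) and afp4 (8.96). Of 71 cytosolic ribosomal protein genes, 70 were at least 2-fold higher, with a median of 2.51 where matched random lists had 0.89. With median-of-ratios scaling the counts were 1807 higher and 2516 lower. At this step that scaling shifts every gene by 0.36 in log2 RPKM, though unevenly in log2(RPKM + 1).

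Between 50%-epiboly and 15-somite, which brackets the laying down of the body axis, hox genes were higher. Of the hox genes, which pattern the body axis, 10 of 11 in paralog groups 1 to 4, 10 of 10 in groups 5 to 8 and 15 of 17 in groups 9 to 13 were at least 2-fold higher, with medians of 2.39, 2.21 and 2.95. HOXB9 had 3.26 and then 33.0 RPKM. The exception in groups 1 to 4 was hoxb1b, already at 54.1 RPKM at 50%-epiboly and at 27.6 RPKM at 15-somite. Somitogenesis and myogenic regulators went both ways, with 9 of 20 at least 2-fold higher and 5 lower (median 0.75), and of 25 skeletal muscle genes 13 were higher and 2 lower (median 1.04). The muscle regulators MYOG (0.105 to 83.6 RPKM) and MYOD1 (2.57 to 48.1 RPKM) were higher, as were the myosin light chain genes myl10 (4.88 to 368 RPKM) and myl13 (1.64 to 138 RPKM). The chaperone gene hsp90aa1.1 and the claudin gene cldni also stood among the 5 largest differences, at 5.83 and 5.77. Of 19 neural progenitor and neurogenesis genes, 10 were at least 2-fold higher, including the proneural gene neurog1 (1.82 to 19.8 RPKM), and of 14 vascular endothelial genes, 9 were, including etsrp, an endothelial transcription factor (0.154 to 36.5 RPKM). Of the 22 mesendoderm and organizer genes 15 were at least 2-fold lower and 0 higher, with a median of -1.66. The pluripotency factor pou5f3 had 197 and then 2.35 RPKM, and nnr had 200 and then 0.383 RPKM. The other 3 large negative differences belonged to VRTN (-5.20), pnp4a (-4.97) and rbp7a (-4.96). At least 4-fold differences numbered 869 higher and 223 lower, or 635 and 484 with median-of-ratios scaling. That scaling shifts every gene by -0.63 in log2 RPKM, though unevenly in log2(RPKM + 1). It takes the median of kidney genes from 0.01 to -0.01, where the list no longer stood apart (percentile 30.22).

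Between 15-somite and Prim-25 muscle, globin, lens, synaptic and pigment genes were higher, while exocrine pancreas enzymes were lower (median -0.72, 11 of 25 at least 2-fold lower and 1 higher). The panel that includes digestive, oocyte and gonad genes was lower with these enzymes, from a median of 1.33 times its Long-pec level to 0.248 times. It was chosen in part for low values at Prim-25. Of 25 skeletal muscle contractile and energy genes 21 were at least 2-fold higher, with a median of 3.46. The calcium buffers pvalb1 (2.69 to 1155 RPKM) and pvalb2 (2.78 to 1144 RPKM) had the largest differences of the named genes, and the fast troponin TNNC2 had 108 and then 902.8 RPKM. All 7 embryonic globins were at least 2-fold higher, with a median of 3.50, and hbbe3 had 232 and then 3603 RPKM. Of 44 lens crystallin and lens fiber genes 30 were higher by that measure and 0 lower, among them CRYBB1 (1.04 to 303 RPKM) and crybb1l2 (0.913 to 162 RPKM). Of 20 synaptic and mature neuron genes 13 were higher (median 1.45), as were 10 of 17 pigment cell genes (median 1.43), where DCT, an enzyme of melanin synthesis, had 1.06 and then 33.4 RPKM. Somitogenesis and myogenic regulators were lower, 13 of 20 by at least 2-fold, with a median of -1.35. The segmentation clock gene her1 had 16.2 and then 0.105 RPKM, tbx6, a factor of the presomitic mesoderm, 29.3 and then 0.313 RPKM, and MYOG 83.6 and then 4.46 RPKM. The posterior regulator cdx4 had 58.8 and then 1.25 RPKM, and krt99 had 240.5 and then 6.62 RPKM. At least 4-fold differences numbered 343 higher and 86 lower.

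The steps from Prim-25 to Long-pec and from Long-pec to Pec-fin held few large differences, 1 higher and 1 lower at the first and 14 higher and 16 lower at the second. These counts depend on the pseudocount, and with 0.1 in place of 1 they were 56 and 28, and 52 and 166. Lens genes were higher at both, with medians of 0.78 and 0.98. The crystallin genes crygm2d21 (11.97 to 62.4 RPKM) and crygm2d16 (2.79 to 15.4 RPKM) were among the largest differences at the second. Muscle genes were lower at Long-pec (median -0.56) and higher at Pec-fin (median 0.96, 12 of 25 at least 2-fold). The muscle myosin myhz1.1 had 16.6, 6.32 and 21.8 RPKM at the 3 stages. Lysozyme, lyz, an enzyme of phagocytes, had 24.3, 69.4 and 136 RPKM, and and3, an actinodin of the fin fold, had 18.0 RPKM at Prim-25 and 53.8 RPKM at Long-pec. Exocrine pancreas enzymes went both ways, with a median of 0.77 at the first step and -1.13 at the second. The trypsin gene prss1 had 4.39, 17.6 and 1.38 RPKM and ela3l 2.69, 10.9 and 0.0678 RPKM, while insl3, a peptide hormone of the gonad, had 1.76, 12.8 and 0.0865 RPKM. Without the exocrine enzymes and the panel of genes with this same course, 0 genes were at least 4-fold lower at Pec-fin and 0 at least 4-fold higher at Long-pec. This follows partly from how the panel was built after seeing the data, on values higher at Long-pec than at Prim-25 and Pec-fin. AMPD1 (0.721 to 11.2 RPKM), an enzyme of muscle purine metabolism, had the largest positive difference at Pec-fin, and cox6b1 and SNORD54 were also among the 5 largest. Among named genes the lowest differences at Long-pec were those of hrc, KLHL31, leng8 and igf2bp1, between -1.46 and -1.29.

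Between Pec-fin and Protruding-mouth, photoreceptor, lens, synaptic and exocrine pancreas genes were higher. The exocrine enzymes had the largest list median, 1.79, with 16 of 25 at least 2-fold higher, but this is measured from the Pec-fin library, where their median level was 0.0678 RPKM against 2.02 at Long-pec and 3.23 at Protruding-mouth. Of 44 lens genes 26 were at least 2-fold higher (median 1.21). Of 30 photoreceptor and phototransduction genes 15 were at least 2-fold higher and 0 lower (median 1.03). The cone opsins opn1sw2 (0.624 to 97.9 RPKM) and opn1lw2 (1.17 to 108 RPKM) and the cone transducin subunit gnb3b (0.250 to 36.1 RPKM) were examples, with rs1a, retinoschisin, at 1.36 and then 104 RPKM. MATN1, a cartilage matrix protein, had the largest difference, from 0.235 to 109 RPKM, and COL10A1, a collagen of skeletal tissue, had 3.50 and then 51.7 RPKM. Of 25 cartilage and bone matrix genes 9 were at least 2-fold higher and 0 lower (median 0.54). Of 19 neural progenitor and neurogenesis genes 7 were at least 2-fold lower and 1 higher (median -0.48). Synaptic genes had a median of 1.42 and circadian clock genes one of 0.91. The clock repressor nr1d2a had 2.196 and then 17.1 RPKM. Of the 62 cell cycle genes 32 were at least 2-fold lower and 0 higher (median -1.01), with PCNA, the DNA polymerase clamp, at 466 and then 182 RPKM. Ribosomal protein genes had a median of -0.97, measured from Pec-fin, where their median level of 1022 RPKM was highest. That level was 692 RPKM at Long-pec, 488 at Protruding-mouth and 848 at 1 week. The hatching enzymes he1.1 (92.0 to 5.17 RPKM) and he1.2 (52.1 to 2.64 RPKM), which digest the egg envelope, and the embryonic globin hbbe3 (2260 to 55.2 RPKM) were lower, while hbae3 stayed within 2-fold at 5359 RPKM. At least 4-fold differences numbered 147 higher and 27 lower, or 106 and 45 with median-of-ratios scaling. That scaling shifts every gene by -0.31 in log2 RPKM, though unevenly in log2(RPKM + 1). It takes the medians of leukocyte genes from 0.02 to -0.10, no longer apart at percentile 3.64, and of housekeeping genes from 0.08 to -0.21.

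Between Protruding-mouth and the 1-week larva, digestive enzymes had the largest differences. Of 25 exocrine pancreas enzymes 23 were at least 2-fold higher and 0 lower, with a median of 6.56. The trypsin-like genes prss59.2 (19.99 to 6610 RPKM) and prss59.1 (3.50 to 3142 RPKM) and the chymotrypsinogen ctrb.1 (13.2 to 4168 RPKM) led, with ctrb.2 and the zymogen granule protein sycn.1. Of 29 intestinal genes 21 were at least 2-fold higher (median 2.08), among them the peptide transporter SLC15A1 (0.571 to 30.6 RPKM) and villin, VIL1 (3.89 to 26.0 RPKM). Photoreceptor genes were higher again (median 1.2, opn1sw2 at 249.7 RPKM), as were crystallins (median 1.61), muscle genes (median 1.17) and clock genes (median 0.88). Of 35 hormone and neuropeptide genes 11 were at least 2-fold higher and 0 lower (median 0.50), and growth hormone, gh1, had 3.29 and then 48.9 RPKM. Of 12 glia and myelin genes 4 were higher and 0 lower (median 0.61), and myelin basic protein, mbpa, had 5.40 and then 70.7 RPKM. Of the 62 cell cycle genes 47 were at least 2-fold lower (median -1.42), with CCNB1 at 26.9 and then 4.54 RPKM. Neural progenitor genes (median -1.06) and hox genes of groups 1 to 4 (-0.95), 5 to 8 (-1.23) and 9 to 13 (-1.25) were lower as well. Of the 7 embryonic globins 4 were at least 2-fold higher and 3 lower (median 1.22). Among them hbae1.1 had 4.54 and then 180.5 RPKM and hbae1.2 3.43 and then 176.8 RPKM, while hbbe3 had 0.522 RPKM at 1 week and hbae3 729 RPKM. Liver genes had a median of 0.39, nuclear oxidative phosphorylation genes 0.00 and heat shock and p53 response genes 0.28, and under median-of-ratios scaling these were -0.02, -0.42 and -0.02. At least 4-fold differences numbered 1040 higher and 88 lower, or 615 and 199 with median-of-ratios scaling. That scaling shifts every gene by -0.43 in log2 RPKM, though unevenly in log2(RPKM + 1).

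**Figure D1:**
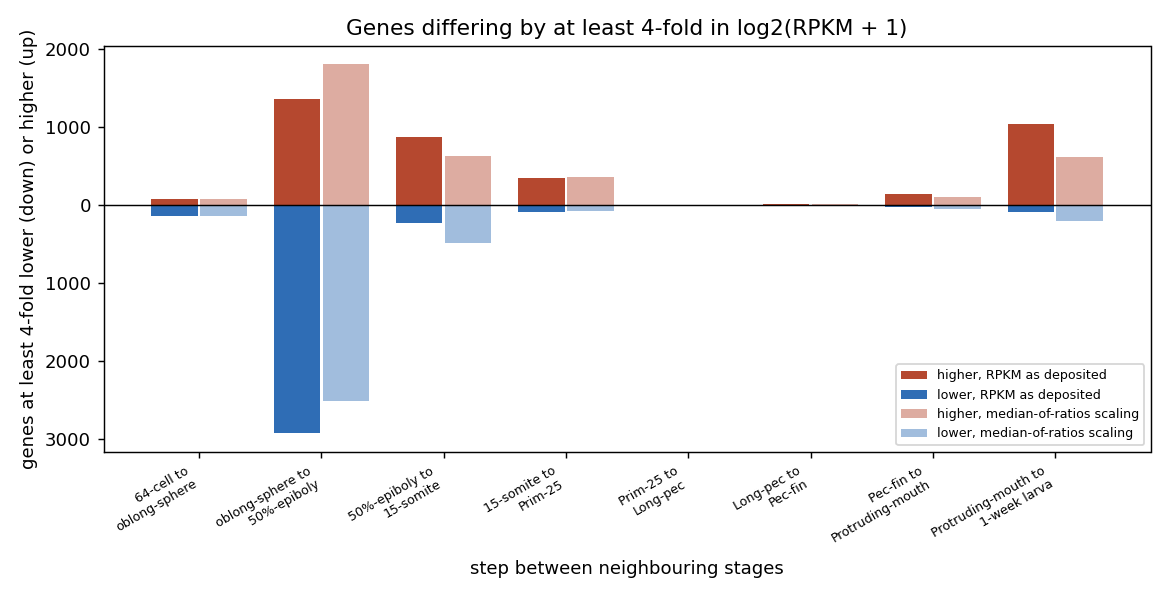
Bars give the number of genes at least 4-fold higher (up) or lower (down) in log2(RPKM + 1) at each of the 8 steps, for RPKM as deposited and after median-of-ratios scaling (paler). The step from oblong-sphere to 50%-epiboly holds the tallest bars, 1365 higher and 2928 lower as deposited.

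**Figure D2:**
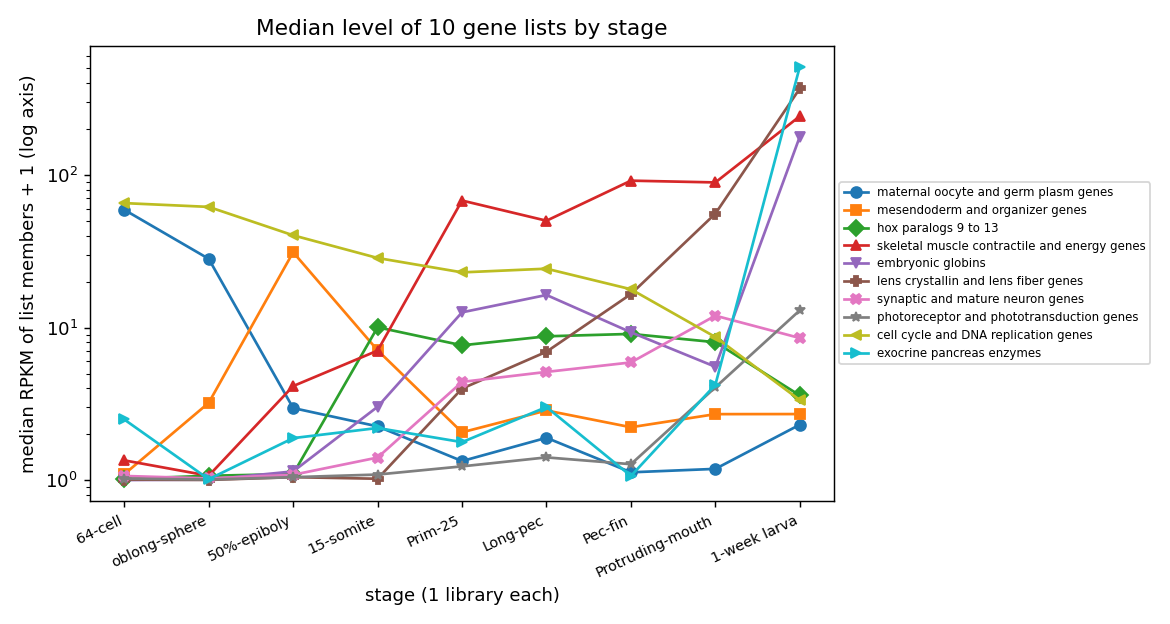
Lines give the median RPKM plus 1 of 10 gene lists, on a log axis, at the 9 stages with 1 library each. Maternal genes are highest at the first stages, hox groups 9 to 13 are highest at 15-somite, and exocrine enzymes, measurable in several earlier libraries, are highest at 1 week.

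Of the 19868 genes, 11701 were at 1 RPKM or more at the 64-cell stage, and 2797 of these (23.9%) were under it at 50%-epiboly. The other 8167 genes first reached 1 RPKM later, with 1788 at 1 week, 1626 at 15-somite and 1550 at 50%-epiboly. The order of these stages depends on the scaling, since with median-of-ratios scaling the counts were 1144, 1306 and 1845. At a threshold of 0.5 RPKM they were 1815, 1835 and 1718. Genes passing a tau index of 0.85 with at least 5 RPKM at their highest stage, which does not require low values at all other stages, numbered 36 at 64-cell, 23 at oblong-sphere, 33 at 50%-epiboly, 1 at 15-somite, 3 at Protruding-mouth and 498 at 1 week. At oblong-sphere they included bmp15, an oocyte growth factor (87.2 RPKM, and 48.8 RPKM at 64-cell), and mxtx2, a regulator of the yolk syncytial layer (12.4 RPKM, and at most 0.803 RPKM elsewhere). At 50%-epiboly they included chrd and pnhd (36.0 RPKM), and at 1 week amy2a, amylase (1148 RPKM), and the elastase ela2l (1015 RPKM). These counts depend on the pseudocount and the scaling. With a pseudocount of 0.1 in place of 1 they were 5 at 64-cell, 1 at oblong-sphere, 4 at 50%-epiboly, 0 at 15-somite, 0 at Protruding-mouth and 180 at 1 week. Median-of-ratios scaling gave 48, 31, 58, 1, 5 and 273 at the same stages.

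Genes of organs that form late were measurable in several early libraries and nearly absent from others. The trypsin gene prss1 had 20.9 RPKM at 64-cell, 0.273 at oblong-sphere, 12.1 at 50%-epiboly, 25.4 at 15-somite, 4.39 at Prim-25, 17.6 at Long-pec, 1.38 at Pec-fin and 48.1 at Protruding-mouth. The elastase ela3l had 13.2, 0.0217, 7.14, 15.6, 2.69, 10.9, 0.0678 and 15.7 RPKM at the same stages. The hormone gene insl3 had 0.313, 0.00566, 7.09, 15.0, 1.76, 12.8, 0.0865 and 0.825 RPKM, and 0.693 RPKM at 1 week.

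**Figure D3:**
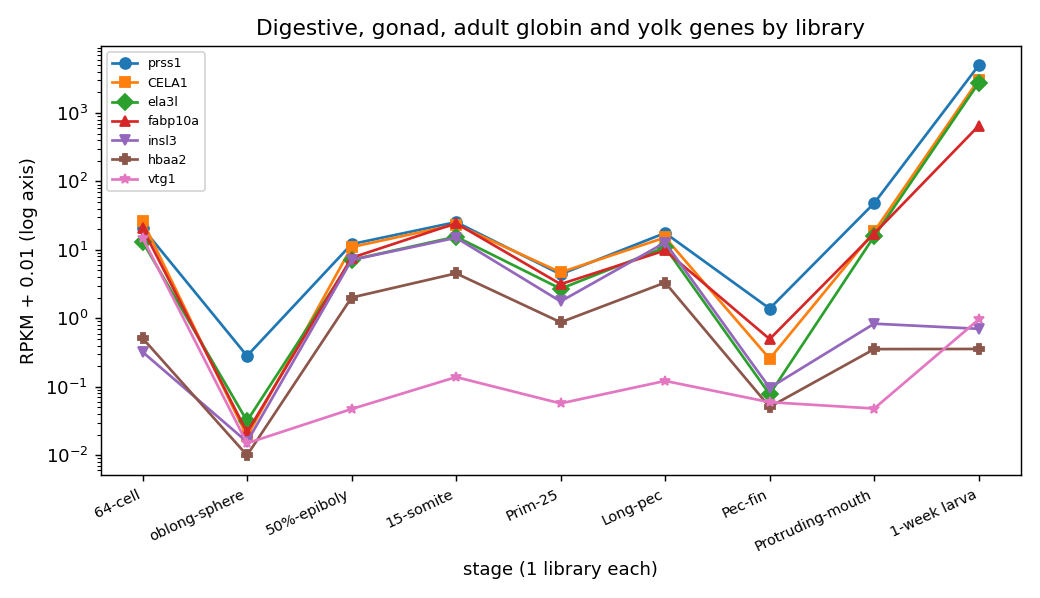
Lines give RPKM plus 0.01, on a log axis, of 7 genes of the pancreas, liver, gonad, adult blood and yolk in the 9 libraries. The oblong-sphere and Pec-fin libraries sit low for the digestive genes, with prss1 at 0.273 and 1.38 RPKM.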

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

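No paired analysis was possible because each stage has 1 library. None of the 80 named-gene differences and none of the 45 list medians of at least 2-fold changed sign under the alternatives run for them, and each of those 45 lists stood apart under all of them. Both groups were chosen for large differences, beyond the reach of the scaling shifts, so a kept sign says little. Lists with smaller medians did change sign under scaling, namely kidney, leukocyte, housekeeping, liver, nuclear oxidative phosphorylation and heat shock genes. Of 160 named-gene values under an alternative, 44 moved by more than 1.5-fold, and of 225 list values 30 did. With the wider matching the medians that moved were early zygotic genes at oblong-sphere (2.1 to 1.28), somitogenesis genes at 50%-epiboly (1.99 to 0.99) and muscle genes at Prim-25 (3.46 to 2.41). Without the filter they were histone genes at 15-somite (-1.26 to -0.62) and lens genes at 1 week (1.61 to 0.90). Scaling by median of ratios moved 5 at 15-somite, among them neural progenitor genes (1.19 to 0.59), and the other moves came with the pseudocount. The alternatives chosen after seeing the data were leaving out the panel and exocrine genes, using each Pec-fin run alone and matching list members more widely. A pseudocount of 0.1 gave more genes past 4-fold at every step. In step order the higher and lower counts were then 314 and 550, 2756 and 4741, 2608 and 442, 989 and 307, 56 and 28, 52 and 166, 867 and 65, and 2227 and 283. With that pseudocount the stage-restricted genes were 5 at 64-cell, 1 at oblong-sphere, 4 at 50%-epiboly, 0 at 15-somite, 0 at Protruding-mouth and 180 at 1 week. Median-of-ratios scaling gave 484 genes lower at 15-somite, 45 lower at Protruding-mouth, and 615 higher and 199 lower at 1 week. It also gave 58 stage-restricted genes at 50%-epiboly, 5 at Protruding-mouth and 273 at 1 week, and 1144 genes with onset at 1 week. Scaling without the 100 most abundant genes gave 242 genes lower at 1 week. Without the panel and exocrine genes 0 genes were higher at Long-pec and 0 lower at Pec-fin, which follows partly from how the panel was built. Pearson correlations of neighbouring stages were 0.967, 0.696, 0.891, 0.923, 0.984, 0.983, 0.947 and 0.82 in order, and Spearman's without the filter 0.937, 0.836, 0.927, 0.95, 0.981, 0.979, 0.964 and 0.892. Without mitochondrially encoded genes the 10 most abundant genes held 3.6%, 2.9%, 8.7%, 8.8%, 11.1%, 10.9%, 11.7%, 10.7% and 11.8% in stage order. Except for the construction of the panel, the cause was not tested. Depth limits little above 1 RPKM, and the spread between separate collections of embryos was not measured.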

Other observations

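All tests in this part were chosen after the patterns they bear on were seen, except the pooled one of gene length and onset. Hormone genes came up at different stages. The pancreatic hormone gene ins had 0.586 RPKM at 15-somite, 6.498 at Prim-25 and 26.2 at Pec-fin, while its paralog insb was highest at 50%-epiboly with 14.8 RPKM. The neuropeptide genes NPY and VIP had 0.438 and 0.762 RPKM at Pec-fin and 13.6 and 16.6 RPKM at 1 week. Clock genes were higher at both of the last steps, by a median of at least 0.88, at percentile 100 of matched random lists each time. NR1D1, a clock repressor, had 0.0851 RPKM at Pec-fin, 4.17 at Protruding-mouth and 46.0 at 1 week. The hour of collection was not given in the sources used here, so this is a hypothesis about stage that collection time could also produce.

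Genes first reaching 1 RPKM at oblong-sphere or 50%-epiboly, pooled as planned, were not shorter than genes with later onset, contrary to the hypothesis tested. Their median recovered length was 1911 bases over 1579 genes, against 1805 bases over 3301 later genes, at percentile 99.79 of random sets. The 2 stages differed, with a median of 2019 bases at 50%-epiboly and 1697 bases at oblong-sphere. The oblong-sphere genes alone lay in the direction of the hypothesis, at percentile 8.26 of random sets of their size, which leaves it open for them. Genes already at 1 RPKM at the 64-cell stage had a median of 2140 bases over 10572 genes. That is longer than for the early and the later genes alike, a difference that was not tested.

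Genes of the pancreas and liver such as prss1, ela3l and fabp10a were present in the 64-cell, 50%-epiboly, 15-somite and Long-pec libraries and low at oblong-sphere and Pec-fin, while oocyte genes such as DDX4 (46.7 RPKM) and ZAR1L (102.4 RPKM) were high at oblong-sphere and low at Pec-fin. A panel of 78 genes was picked on the Prim-25, Long-pec and Pec-fin libraries, and its ratio of 15-somite to 50%-epiboly was then examined in 5 gene sets. Of the panel genes outside the exocrine list, 95.6% exceeded 4 times the share that carry-over from the 1-week library would bring. Maternal genes such as zp3a.1 exceed it through their own RNA. Carry-over is argued against for genes such as insl3, with 15.0 RPKM at 15-somite and 0.693 RPKM at 1 week. The genes under the bound were the pancreatic enzymes ctrb.1, ctrb.3 and CEL, for which carry-over stays open. The spread of the whole panel (SD 1.34) lay at percentile 72.55 of matched random sets, or 75.48 without the exocrine genes, so not all of the panel's RNA can come from 1 source. The panel holds maternal and early zygotic transcripts such as zp3e (463 RPKM at 64-cell) and nnr, whose own RNA widens this spread whatever the origin of the rest, so those values leave both a common source and expression of each gene at its own stage open for the others. In a further set tried after that result, the 40 tested panel genes under 0.5 RPKM at oblong-sphere, the SD was 0.39 at percentile 0.00, against random sets under the same limit, and 0.44 at the same percentile for the 30 outside the exocrine list, which still include pancreatic enzymes such as ctrb.1 beside insl3 and hbaa2. RNA of older fish in the 50%-epiboly and 15-somite libraries may account for that part, but the set was narrowed after the first answer. The exocrine enzymes alone (percentile 0.28) would keep 1 ratio under shared regulation as well. The 64-cell library was not part of this ratio. There insl3 had 0.313 RPKM beside 13.2 for ela3l, against 7.09 and 7.14 at 50%-epiboly, so these genes do not show the same mix at 64-cell.

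The 1-week library had 17381 genes at 1 RPKM or more, against 15563 at Protruding-mouth. Depth is argued against by a ratio of mapped reads of 0.995. A uniform background is argued against by 163 olfactory receptor genes, whose median difference was 0.020 RPKM. The 30th percentile of all genes differed by 0.297. The olfactory medians were 0.014 and 0.041 RPKM, a relative rise close to the 3.09 times of that percentile. These genes thus bear only on a background that adds the same RPKM to every gene. After median-of-ratios scaling the ratio of detected genes was 1.005, so at that threshold scaling and a broader set of expressed genes cannot be told apart, since that scaling assumes that most genes keep their level. Scaling is argued against for the low values, where the 30th percentile of all genes was 0.440 RPKM against 0.142 and still at least 2.29 times as high after scaling, and genes at 0 numbered 1974 against 3596. Small nucleolar RNA genes, whose products lack a poly(A) tail, were higher by a median difference of 2.42 over 36 genes. Their median levels were 7.67 and 88.4 RPKM. More such RNA in this library would give that. A low Protruding-mouth value may also have a part, but 1 such gene, SNORD54, shows this only weakly. It had 11.99 RPKM at Long-pec, 56.0 RPKM at Pec-fin and 5.78 RPKM at Protruding-mouth. Its drop after Pec-fin thus starts from a raised value there. Genes of up to 600 bases as a whole differed by a median of 0.275 at 1 week, so gene length may have a part too. More cell types at 1 week, the biological explanation, was not tested.

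Ribosomal protein genes were higher at 50%-epiboly than at oblong-sphere. For the 64 with a recovered length the median was 2.53, above the range of 1.35 to 2.31 for others matched on expression and length. Length thus accounts for part of the difference at most. Under median-of-ratios scaling the median over all members was 2.87. That scaling raises log2 RPKM differences by 0.36 at this step, so it could only enlarge this one. The value therefore does not decide whether scaling has a part. Longer poly(A) tails on the same transcripts could raise their yield in poly(A) libraries, and that and new transcription cannot be told apart here because the values hold no tail lengths.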
